A study of Mus musculus with 15 samples.

How the data were processed

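Small RNA was sequenced from 15 mouse libraries in 5 groups of 3. MM3MG is a normal mammary epithelial line from BALB/c mice, and MM3MG-Her2 is the same line transduced with retroviral particles carrying Neu, the rat form of Her2. TUBO is a tumour line from mice that carry a Neu transgene, sampled as cells, as exosomes isolated from the culture supernatant, and as the supernatant left after exosome isolation. All cultures were in DMEM with 10% FCS, per the labels' protocols. Whether replicates are separate cultures or repeated libraries of one culture is not given in the sources used here, so the p-values measure the spread between these samples, which is technical if they came from one culture.

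Per the labels' protocols, total RNA was isolated with TRIzol, a 3' adapter and a 5' adapter were ligated, the product was reverse transcribed and amplified by PCR, and bands corresponding to miRNA inserts were taken from a gel. No molecular identifiers are named there. The deposited values are counts: each library lists distinct insert sequences with the whole number of reads that had that sequence, and the authors deposited no miRNA name, alignment or normalised value beside them. The values themselves show that adapters had been removed, that identical reads had been collapsed, and that uncalled bases had been kept. The trimming tool, the miRNA annotation and the genome build behind the study's own results are not given in the sources used here.

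Reads were assigned to miRNAs from sequence alone. The reference was GENCODE M21 on GRCm38, which holds 2202 miRNA hairpins, of which 1178 have a miRNA name and 1024 do not. Inserts of 18 to 26 bases were matched to the hairpins that have a miRNA name: the first 18 bases had to match, uncalled bases were taken as matching, and up to 2 differences were allowed after them. RNAfold 2.7.2 placed each tag on the 5p or the 3p arm. Arms that shared at least 50% of their reads with another arm were merged into 1 feature, which gave 23 merged features with a joint name. Across the 15 libraries there were 627951 distinct sequences and 6892924 reads, of which 4366443 were assigned to 857 hairpin arms. The feature called miR-92-3p is the one usually written miR-92a-3p. Near-identical paralogs (within let-7, miR-30, miR-29, miR-181 and miR-17-92) are uncertain at the level of single members, since a substitution or a trimmed end can move a read between them. The match rule was chosen after the sequences had been seen and before any group was compared. Reads that matched no miRNA were compared with other annotated RNA of the same reference, which holds no 45S ribosomal RNA and no nuclear tRNA genes, so the source of reads that matched nothing was not assigned.

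Abundance is given in CPM over the miRNA reads of each library, without TMM scaling, as mean and SD over the 3 libraries of a group. Depth ranged from 196152 reads (TUBO supernatant, replicate 2) to 710902 reads (TUBO cells, replicate 3), and miRNA reads from 58779 to 536637 in the same libraries. A miRNA with 0 reads in a group has a floor of 3 reads over that group's miRNA reads, and a fold against it is a lower bound. With 1 to 3 reads in the lower group the ratio of CPM is given with its 95% counting interval. Since PCR reads without molecular identifiers are not independent molecules, intervals and floors cover counting error only.

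Counts were compared in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, robust quasi-likelihood fit and F-test) with Benjamini-Hochberg adjustment and a threshold of 0.05. The 9 cell libraries were fitted together for MM3MG-Her2 against MM3MG, TUBO cells against MM3MG and TUBO cells against MM3MG-Her2. A second fit took the 9 TUBO-derived libraries for exosomes against cells, exosomes against supernatant and supernatant against cells. No replicate block was used in the main fits. Deviations from group means were correlated between libraries of the same number. For exosomes against supernatant this gave 0.0662, 0.117 and 0.193, against a mean of −0.0599 for different numbers, so pairing of these fractions stays open. In the other comparisons same-number correlations lay between −0.164 and 0.0612. Every log2 fold change is the first-named group minus the second, with its standard error, n = 3 per group, and every adjusted p of a single miRNA comes from the edgeR test. A miRNA is said to have risen or fallen only when its adjusted p was under 0.05. Shares of reads were compared with exact two-sided permutation tests, for which 3 libraries against 3 cannot give a p below 0.1.

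Comparisons, lists and the rule for named miRNAs were set before the data were examined. In the comparisons of MM3MG-Her2 with MM3MG, TUBO cells with MM3MG, exosomes with cells and exosomes with supernatant, the rule took the 8 largest rises and the 8 largest falls among miRNAs past the threshold with at least 100 CPM in either group and no overlap between the groups' libraries. It took 3 each way in the other comparisons. It added miR-9-5p and miR-30a-5p everywhere, the 3 most abundant miRNAs of each group, and up to 4 members of each list with the smallest adjusted p. Names outside the rule were chosen after their values were seen. They are the members of counts of 5 or fewer, the small RNA genes that are not miRNAs, the miRNAs with a substitution in exosomes, and examples of opposite changes.

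The 13 fixed lists were progesterone receptor candidates, epithelial (miR-200 family, miR-203, miR-205), mesenchymal and stromal, let-7 family, miR-17-92 and paralogous clusters, oncomiRs and invasion, tumour suppressor, blood cell and serum, muscle, neuronal, the Dlk1-Dio3 imprinted cluster on chromosome 12, the Sfmbt2 intronic cluster on chromosome 2, and star strands. They were written from general knowledge, without these samples. Lists with at least 3 tested members were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. camera compares a list with all other tested miRNAs. filterByExpr keeps a miRNA found in any group of a fit. List members scarce in one group are thus tested only where another group holds them, which favours a common direction.

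Alternatives tried were RLE, upper-quartile and library-size scaling, DESeq2 1.42.0 and limma voom, other filters on low counts, the groups compared alone or all 15 libraries in one fit, the 5 most abundant miRNAs left out, a 2-fold minimum, the replicate number as a block, thinning to the smallest library, and leaving out each replicate. Alternatives added after seeing the data were exact matches alone, inserts of 20 to 24 bases, hairpins without a miRNA name added, and the blood list left out before scaling. The edgeR steps were tested on simulated counts for 857 miRNAs, 200 of them changed. At a 2-fold change the share recovered was 84.2% for MM3MG-Her2 against MM3MG, 91.2% for TUBO cells against MM3MG, 90.4% for TUBO cells against MM3MG-Her2, 92.9% for exosomes against cells, 82.0% for exosomes against supernatant and 80.4% for supernatant against cells. At 1.5-fold it was 65.5%, 66.1%, 52.8%, 32.2%, 28.3% and 25.0% in the same order. Of the unchanged miRNAs 0 of 76, 2 of 81, 5 of 68, 0 of 41, 4 of 46 and 1 of 38 were called. Tables and figures were made with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. All deposited libraries were used.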

Results

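The series measured small RNA in 15 mouse libraries, 3 from each of MM3MG cells, MM3MG-Her2 cells, TUBO cells, TUBO exosomes and TUBO supernatant, to find miRNAs that may regulate the progesterone receptor in Her2 lines and in what they secrete. Total reads were 417572, 643361 and 453668 for MM3MG replicates 1 to 3, 463105, 475769 and 341106 for MM3MG-Her2, 653871, 525422 and 710902 for TUBO cells, 583658, 428335 and 498402 for exosomes, and 228034, 196152 and 273567 for supernatant. The share of reads assigned to miRNAs was 76.3% ± 3.70 (SD, n = 3) in MM3MG, 51.9% ± 2.42 in MM3MG-Her2, 76% ± 0.491 in TUBO cells, 59.0% ± 1.66 in exosomes and 30.4% ± 2.54 in supernatant. Reads matching none of the annotated RNA made up 62.6% ± 2.92 of the supernatant libraries, and their source was not assigned. Inserts of 20 bases or fewer made up 10.2% ± 1.15 of reads in MM3MG, 16.1% ± 1.71 in MM3MG-Her2, 10.1% ± 0.279 in TUBO cells, 15.9% ± 2.09 in exosomes and 28.9% ± 4.70 in supernatant. Replicates differed by more than sampling noise of reads in every pair, with a chi-square of 4.32 to 88.9 times its degrees of freedom, highest between exosome replicates 1 and 3. The chi-square takes PCR reads as independent molecules, so it can overstate this excess. The most abundant miRNAs were miR-21a-5p, miR-143-3p and miR-199a-3p/miR-199b-3p in MM3MG (201900, 104001 and 74805 CPM), and miR-21a-5p, miR-92-3p and miR-143-3p in MM3MG-Her2 (294102, 105638 and 61420 CPM). In TUBO cells they were miR-30a-5p, miR-21a-5p and miR-92-3p (145125, 77807 and 63629 CPM), and in exosomes miR-30a-5p, miR-21a-5p and miR-182-5p (98833, 75800.3 and 65780 CPM). Supernatant was led by miR-92-3p at 247532 ± 5936 CPM (SD, n = 3), followed by let-7c-5p and miR-25-3p (99017 and 95579.9 CPM).

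**Figure D1:**
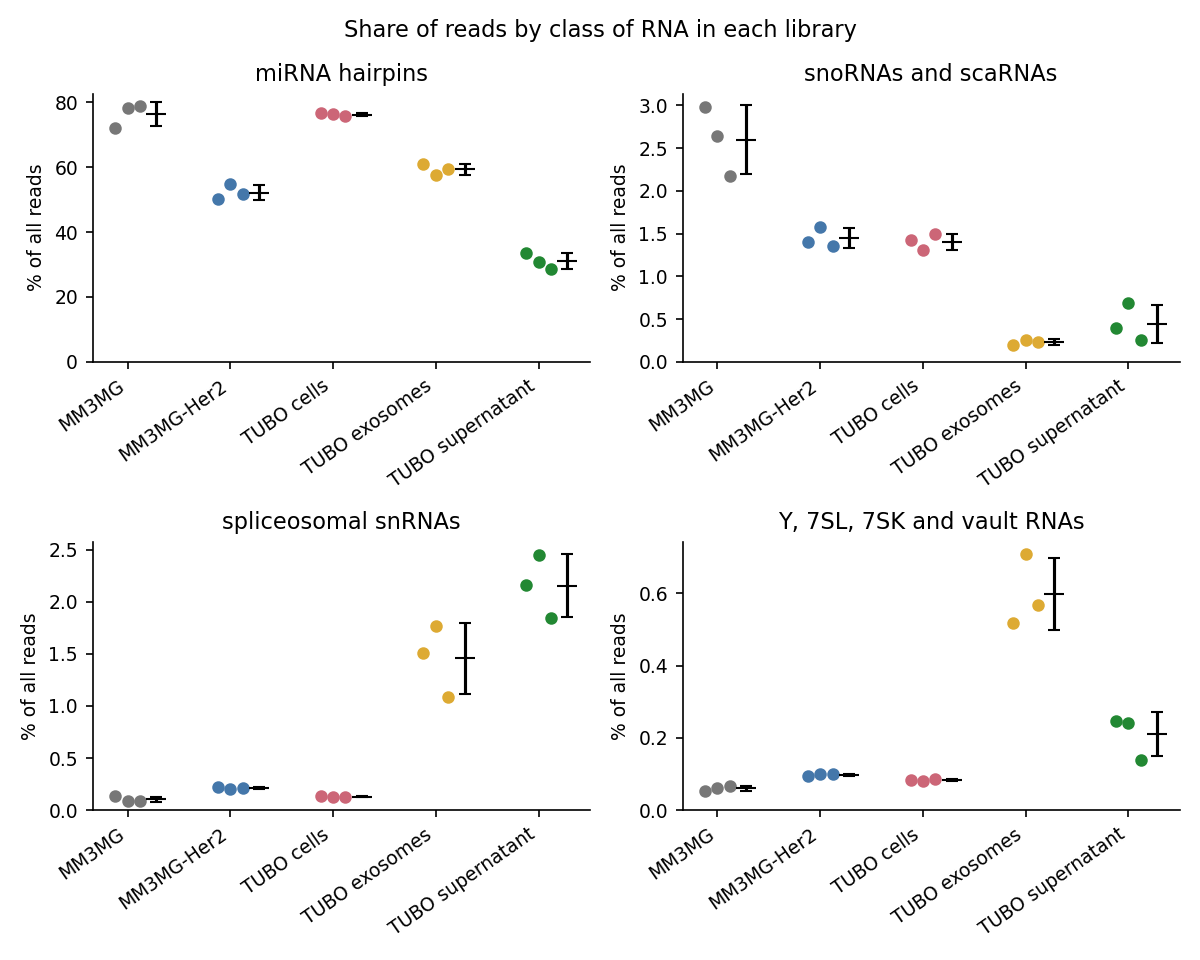
Share of all reads (%) matching miRNA hairpins, snoRNAs and scaRNAs, spliceosomal snRNAs, and Y, 7SL, 7SK and vault RNAs in each library; points are libraries, and the horizontal mark with bars is the mean ± SD of 3. snRNA fragments made up 1.46% of reads in exosomes and 2.15% in supernatant, against 0.130% in TUBO cells.

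The comparison of MM3MG-Her2 with MM3MG asks what differs in a normal mammary line after transduction with the Neu retrovirus. Their libraries differed too. Reads matching no annotated RNA made up 39.9% in MM3MG-Her2 and 16.9% in MM3MG, and inserts of 20 bases or fewer 16.1% and 10.2%. Whether RNA quality or preparation adds to the changes was not tested. Among miRNAs with at least 100 CPM in either group, the largest falls were in miRNAs of the Dlk1-Dio3 imprinted cluster on chromosome 12, which is expressed from the maternal chromosome in embryonic and stem cells. miR-127-3p (hairpin at chromosome 12, 109592846 to 109592915, GRCm38, antisense to an Rtl1 exon) fell by 6.24 ± 0.20 on the log2 scale (SE, n = 3 per group, adjusted p = 7.9e-16), from 6566 to 82.0 CPM. miR-379-5p fell by 6.29 ± 0.27 (adjusted p = 2.0e-13), and miR-10b-5p, a miRNA of the Hoxd cluster on chromosome 2, by 6.09 ± 0.41 (adjusted p = 3.8e-06). miR-7-5p rose by 3.05 ± 0.17 (adjusted p = 5.0e-12) to 2388 CPM, miR-503-5p by 2.56 ± 0.14, and miR-155-5p, an oncogenic miRNA of immune cells, by 2.53 ± 0.28 (adjusted p = 1.1e-07). miR-30a-5p (Mir30a, chromosome 1, 23272269 to 23272339) rose by 1.29 ± 0.09 (adjusted p = 1.5e-10), from 13598 ± 342 to 32122 ± 2560 CPM (SD, n = 3). miR-9-5p fell by 1.60 ± 0.15 (adjusted p = 6.9e-09), from 311 ± 15.4 to 98.7 ± 8.54 CPM. Its sequence TCTTTGGTTATCTAGCTGTATGA is shared by 3 hairpins on chromosomes 3, 7 and 13, so its locus is open.

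Of 279 miRNAs tested between MM3MG-Her2 and MM3MG, 175 passed the threshold, 86 higher and 89 lower, and the libraries of both groups did not overlap for 184 (65.9%, against 10% by chance). Other large rises were miR-6539-5p (4.65 ± 0.27, adjusted p = 6.7e-12), miR-212-3p (3.87 ± 0.48, adjusted p = 6.0e-07), miR-6236-5p (3.08) and miR-3473b-3p/miR-3473e-5p (2.56). miR-5126-3p had 77 reads against 2, a ratio of 67.1 with a 95% counting interval of 18 to 564. Whether reads assigned to miR-6236, miR-6539, miR-5126 and miR-3473 are miRNAs or fragments of other RNAs was not tested. Other large falls, all from the Dlk1-Dio3 region, were miR-434-5p (−5.55), miR-136-3p (−5.51), miR-127-5p (−5.36) and miR-411-5p (−5.19), and miR-329-5p had 1 read against 119, a ratio of 68.2 with a counting interval of 12 to 2718. Leaving out MM3MG replicate 1 or MM3MG-Her2 replicate 2 moved the median of all tested miRNAs from 0.01 to −0.45 and −0.39, with 56 and 42 rises against 134 and 114 falls. Without MM3MG replicate 1, miR-155-5p was 1.89, miR-212-3p 3.09, miR-434-5p −6.27, miR-136-3p −6.12 and miR-411-5p −5.81. Without MM3MG-Her2 replicate 2, miR-9-5p was −2.20, miR-212-3p 3.05 and miR-136-3p −6.12, and without replicate 1 miR-434-5p was −6.28 and miR-329-5p −8.45. RLE scaling put that median at −0.13, so changes near it have no settled direction.

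Among fixed lists, all 14 tested members of the Dlk1-Dio3 cluster fell in MM3MG-Her2, with a median of −4.47 (14 adjusted over the list alone; camera adjusted p = 8.9e-10, adjusted p = 0.0559 with an estimated correlation). The miR-17-92 list, growth-promoting miRNAs driven by Myc and E2F, had 8 of 9 members higher and 0 lower (8 adjusted over the list alone), with miR-92-3p at 1.92 ± 0.09, miR-20a-5p at 2.37 ± 0.14 and a median of 1.60 (camera adjusted p = 1.9e-04, adjusted p = 0.0559 with an estimated correlation). Without MM3MG replicate 1, miR-92-3p was 1.27 and miR-20a-5p 1.71. Star strands, the less abundant arms of hairpins, had 12 of 21 higher and 1 lower (13 adjusted over the list alone), such as miR-16-3p (2.02) and miR-92-5p (2.52; 1.90 without MM3MG replicate 1), with camera adjusted p = 0.00935 and adjusted p = 0.0559 with an estimated correlation. The mesenchymal and stromal list had 5 of 8 lower and 0 higher (5 adjusted over the list alone), including miR-143-3p (−0.71) and miR-199a-5p (−1.46), with a median of −0.85. Its camera adjusted p was 0.0494, 0.0846 without MM3MG-Her2 replicate 3, and adjusted p = 0.547 with an estimated correlation.

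Progesterone receptor candidates went both ways in MM3MG-Her2: 5 of 13 rose, among them miR-30a-5p, and 5 fell, among them miR-9-5p and miR-181a-5p (−1.11 ± 0.10; −1.78 without MM3MG replicate 1). Their median was −0.29, 10 passed adjusted over the list alone, and camera gave an adjusted p of 0.95. OncomiRs had 5 of 13 higher and 7 lower (12 adjusted over the list alone), with miR-155-5p at 2.53 and miR-182-5p at −1.37. In the tumour suppressor list 3 of 11 rose and 5 fell (9 adjusted over the list alone), such as miR-29a-3p (−0.93). The let-7 list had 2 of 9 higher and 3 lower (5 adjusted over the list alone), led by let-7i-5p (−0.86), and the neuronal list 1 of 5 higher, miR-132-3p (2.42; 1.66 without MM3MG replicate 1), and 1 lower, miR-138-5p (−4.72; −5.50 without MM3MG-Her2 replicate 2), 2 of them adjusted over the list alone. Epithelial miRNAs were near the detection limit in both MM3MG lines: 1 of 7 rose, miR-200c-3p with 6 reads against 2, a ratio of 5.23 with a counting interval of 0.935 to 53.0 (log2 2.22; 1.35 and no longer past the threshold without MM3MG replicate 1, 1.13 without MM3MG-Her2 replicate 3), and 1 fell, miR-203-3p with 0 reads, at least 3.25-fold lower, with 1 adjusted over the list alone. Camera adjusted p was 0.95 for each list of this paragraph; it pointed down for epithelial miRNAs, whose median was 0.25, or 0 at bounds, and up for neuronal ones, whose median was 0. With fewer than 3 members tested, no list test was made for blood cell and serum miRNAs (miR-3107-5p/miR-486-5p, −0.57; −1.18 without MM3MG-Her2 replicate 2), muscle (miR-206-3p, 1.02, not past the threshold with DESeq2, at 0.71, or without MM3MG-Her2 replicate 2, at 0.52) or the Sfmbt2 cluster (0 of 2 passed by edgeR).

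TUBO cells were compared with MM3MG to find what a Her2-driven tumour line has in common with or apart from normal mammary cells. The miR-200 family, which keeps cells epithelial by repressing Zeb1 and Zeb2, separated both lines: miR-200b-3p rose by 10.49 ± 0.23 (SE, n = 3 per group, adjusted p = 1.6e-19) to 6460 CPM, and miR-200a-3p by 10.25 ± 0.21 (adjusted p = 5.6e-20) to 10571 CPM. miR-200c-3p (chromosome 6, 124718322 to 124718390) had 2 reads in MM3MG and 4331 CPM in TUBO cells, a ratio of 2532 (95% counting interval 701 to 20911), and its fitted log2 change went from 11.32 to 10.52 without MM3MG replicate 1. miR-214-3p (chromosome 1, 162223368 to 162223477, in an exon of Dnm3os), a stromal miRNA, had 0 reads in TUBO cells and was at least 991-fold lower. miR-9-5p rose by 7.79 ± 0.13 (adjusted p = 3.0e-21), from 311 to 55599 ± 1150 CPM (SD, n = 3), and miR-30a-5p by 3.73 ± 0.10 (adjusted p = 3.5e-18), from 13598 to 145125 ± 4999 CPM. miR-127-3p fell by 10.21 ± 0.27 (adjusted p = 2.8e-18).

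**Figure D2:**
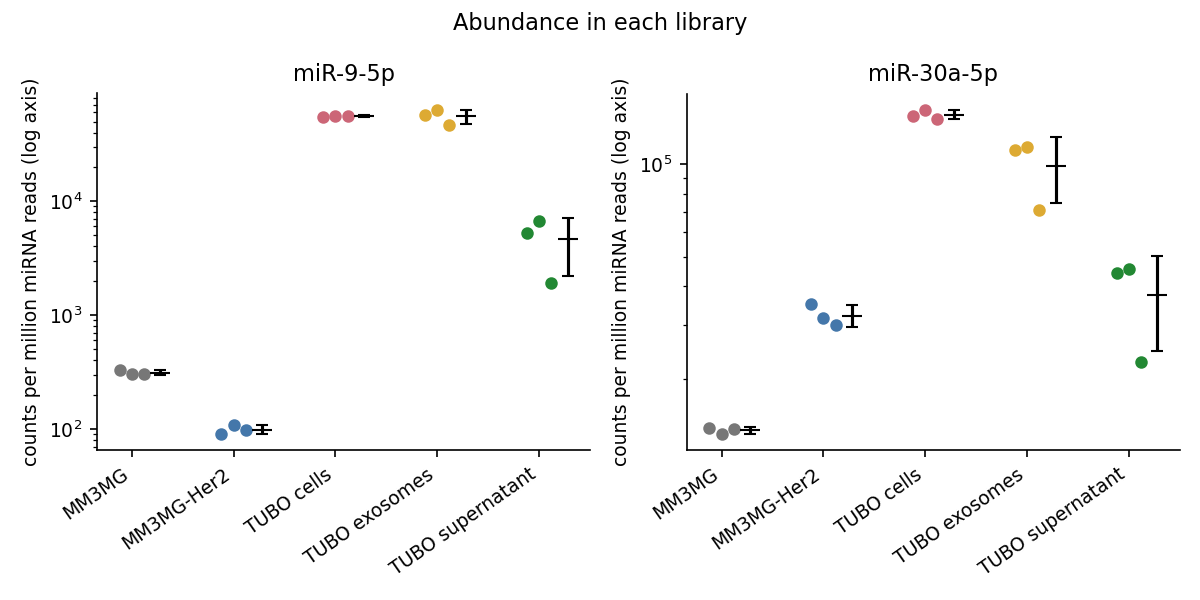
CPM of miR-9-5p and miR-30a-5p in each library on a log axis; points are libraries, and the horizontal mark with bars is the mean ± SD of 3. miR-9-5p averaged 311 CPM in MM3MG, 98.7 in MM3MG-Her2, 55599 in TUBO cells, 55501 in exosomes and 4657 in supernatant.

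Of 279 miRNAs, 231 passed between TUBO cells and MM3MG, 125 higher and 106 lower, and 229 did not overlap (82.1%, against 10% by chance). miR-204-5p rose by 10.45 ± 0.18 (adjusted p = 3.2e-21) to 29808 CPM. miR-141-3p, with 1 read in MM3MG, had a ratio of 2616 (counting interval 469 to 103370), and miR-429-3p, with 2 reads, 1247 (345 to 10303). miR-200a-5p and miR-135b-5p, with 0 reads in MM3MG, were at least 169-fold and at least 78.6-fold higher. Among falls, miR-136-3p, miR-382-5p, miR-434-3p, miR-434-5p and miR-299a-3p had 0 reads in TUBO cells and were at least 246-fold, 231-fold, 203-fold, 187-fold and 155-fold lower. miR-199a-5p had 3 reads, a ratio of 1364 (466.4 to 6619). Of these, the fitted change of miR-141-3p went from 11.13 to 10.42 and 12.73 without MM3MG replicates 1 and 2, and that of miR-199a-5p from −9.95 to −12.96 and −9.30 without TUBO cells replicates 2 and 3. The balance of rises and falls moved with the scaling: 54.1% of calls were rises with a median change of 0.22 under TMM, 39.1% and −0.43 with upper-quartile scaling, and 44.3% and −0.19 with RLE. Without MM3MG replicate 1 they were 41.6% and −0.33.

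All 7 epithelial miRNAs rose in TUBO cells (7 adjusted over the list alone), with a median of 10.29 and camera adjusted p = 4.3e-08 (adjusted p = 0.0890 with an estimated correlation). All 8 mesenchymal and stromal miRNAs fell (8 adjusted over the list alone), with a median of −9.09, or −8.92 with members at the floor set to their bound (camera adjusted p = 6.1e-04, adjusted p = 0.216 with an estimated correlation). The summed share of this list fell less, from 19.5% of miRNA reads in MM3MG to 4.73% in TUBO cells, where miR-143-3p still had 46981 CPM. Dlk1-Dio3 miRNAs all fell, 14 of 14 (14 adjusted over the list alone), with a median of −9.37, or −7.45 with 9 at their bound (camera adjusted p = 3.8e-08, adjusted p = 0.0890 with an estimated correlation). Progesterone receptor candidates had 10 of 13 higher and 3 lower (13 adjusted over the list alone), with miR-9-5p, miR-30a-5p, miR-30c-5p (3.34) and miR-181b-5p (2.14) rising most and miR-26a-5p falling by 1.32. Their median was 0.73 with a camera adjusted p of 0.0562, which was 0.0318 without MM3MG replicate 3 and 0.0391 without TUBO cells replicate 3, and adjusted p = 0.292 with an estimated correlation. Together they made up 31.2% ± 0.625 of miRNA reads in TUBO cells and 10.6% ± 1.16 in MM3MG (SD, n = 3, exact permutation p = 0.1, the smallest possible). Without MM3MG replicate 1, miR-30c-5p was 2.67 and miR-181b-5p 1.44.

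The miR-17-92 list had 7 of 9 higher in TUBO cells and 0 lower (7 adjusted over the list alone), with miR-93-5p at 2.16 and miR-92-3p at 1.45. Its camera adjusted p was 0.0701, and 0.0185, 0.0432 and 0.0226 without MM3MG replicate 1, MM3MG replicate 2 and TUBO cells replicate 2. OncomiRs had 7 of 13 higher and 4 lower (11 adjusted over the list alone), with miR-210-3p at 2.15, miR-183-5p at 1.78 and miR-21a-5p at −1.06. In the tumour suppressor list 5 of 11 rose and 6 fell (11 adjusted over the list alone), including miR-34a-5p (5.07) and miR-34c-5p (−3.28). let-7 members had 5 of 9 higher and 1 lower (6 adjusted over the list alone), of which let-7b-5p (0.73) and let-7c-5p (0.66) did not pass without MM3MG replicate 1 (0.11 and 0.04), the neuronal list 3 of 5 higher and 2 lower (5 adjusted over the list alone), and star strands 12 of 21 higher and 3 lower (15 adjusted over the list alone), led by miR-30a-3p (3.89). Camera adjusted p was 0.720 for oncomiRs, 0.586 for tumour suppressors and let-7, 0.683 for neuronal and 0.331 for star strands. Summed shares of miRNA reads went against the member counts for let-7 (13.3% in TUBO cells, 14.6% in MM3MG) and oncomiRs (16.5% and 26.7%). They went with them for miR-17-92 (10.3% and 5.56%), star strands (0.781% and 0.364%) and tumour suppressors (1.17% and 2.72%). The neuronal share was 0.0506% and 0.0515%. Untested as lists, miR-3107-5p/miR-486-5p fell by 2.65, miR-206-3p had 0 reads in TUBO cells and was at least 61.5-fold lower, and both Sfmbt2 members, miR-669c-5p and miR-669a-3p/miR-669o-3p, fell at least 45.4-fold and 18.2-fold.

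Changes from MM3MG were set side by side to ask what both Her2 lines share. Among miRNAs past the threshold in both, 109 changed in the same direction, 54 higher and 55 lower, against 72.3 if the calls were independent. Since MM3MG served as control in both, changes were also simulated with no true effect. The correlation of the changes was 0.458 against 0.479 simulated. Where nothing changed the shared control makes up much of the spread, so this simulated correlation is high by design. It cannot judge the real one. The covariance of the changes was 4.13, against 0.0364 simulated and 0.0594 at most, so little of it came from the spread between MM3MG libraries. The simulation holds no trait of the MM3MG line itself, which enters both changes alike. It cannot tell changes shared by the Her2 lines from such a trait. Part of the excess of shared calls may come from the shared control. miR-30a-5p, miR-92-3p, miR-7-5p and the Dlk1-Dio3 miRNAs moved alike. Another 40 moved in opposite directions, such as miR-9-5p (−1.60 and 7.79), miR-182-5p (−1.37 and 1.24), miR-146b-5p (−2.16 and 3.02), miR-196a-5p (0.70 and −7.80) and miR-21a-5p (0.60 and −1.06). The last is the most abundant miRNA of MM3MG.

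**Figure D3:**
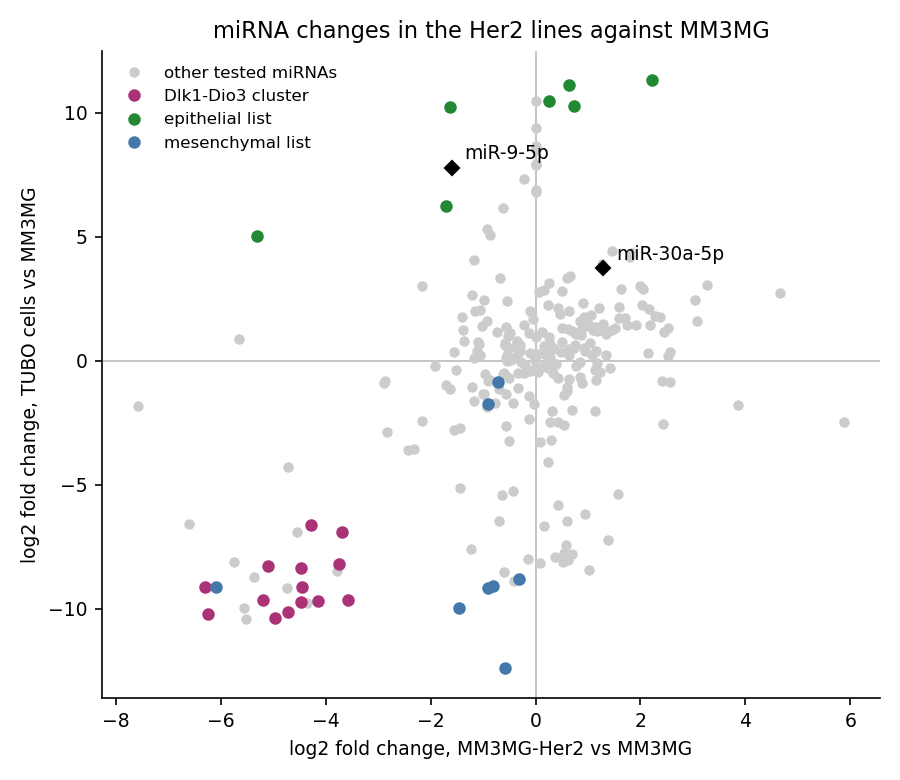
log2 fold change against MM3MG of each tested miRNA in MM3MG-Her2 (x axis) and in TUBO cells (y axis), with the Dlk1-Dio3, epithelial and mesenchymal lists coloured. All 14 Dlk1-Dio3 miRNAs fell in both, and the 7 epithelial miRNAs rose in TUBO cells; fitted values of miRNAs with 3 or fewer reads in a group depend on the prior count and are not bounds.

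TUBO cells and MM3MG-Her2, both carrying Neu, were compared directly, which also tests whether their changes from MM3MG differ. Epithelial miRNAs stood furthest apart: miR-200a-3p had 2 reads in MM3MG-Her2, a ratio of 3512 (95% counting interval 972 to 28999), miR-141-3p had 1, a ratio of 1500 (269 to 59283), and miR-200a-5p had 0 and was at least 96.7-fold higher in TUBO cells. miR-214-3p and miR-206-3p had 0 reads in TUBO cells, at least 640-fold and 124-fold lower, and miR-218-5p had 1, a ratio of 684 (122 to 27113). miR-9-5p was higher in TUBO cells by 9.39 ± 0.15 (SE, n = 3 per group, adjusted p = 8.2e-22) and miR-30a-5p by 2.44 ± 0.09 (adjusted p = 2.3e-15). Without MM3MG-Her2 replicate 1, miR-9-5p was 8.79, and without replicate 3 miR-30a-5p was 1.84. Fitted changes of miRNAs with 1 or 2 reads moved too: miR-200a-3p from 11.88 to 10.96 without MM3MG-Her2 replicate 3, miR-141-3p from 10.49 to 12.60 and 9.63 without MM3MG-Her2 replicates 1 and 3, and miR-218-5p from −8.64 to −9.28 without MM3MG-Her2 replicate 1 and −10.33 without TUBO cells replicate 2. Of 279 miRNAs, 207 passed, 93 higher and 114 lower, and 224 did not overlap (80.3%, against 10% by chance). The median over all miRNAs was −0.13, and −0.62 with upper-quartile scaling, −0.39 with library size, −0.29 with RLE, and −0.66 without MM3MG-Her2 replicate 1 or 3.

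All 7 epithelial miRNAs were higher in TUBO cells than in MM3MG-Her2 (7 adjusted over the list alone), with a median of 10.24, or 9.56 at bounds (camera adjusted p = 2.8e-09, adjusted p = 0.0845 with an estimated correlation), and 6 of 8 mesenchymal miRNAs were lower and 0 higher (6 adjusted over the list alone), with a median of −8.24, or −6.99 at bounds (camera adjusted p = 0.00273, adjusted p = 0.301 with an estimated correlation). The mesenchymal list held 4.73% of miRNA reads in TUBO cells and 10.6% in MM3MG-Her2. Progesterone receptor candidates had 8 of 13 higher and 4 lower (12 adjusted over the list alone), with a median of 1.53 and camera adjusted p = 0.0243, which was 0.0719 and 0.0929 without MM3MG-Her2 replicates 1 and 3, 0.0940 with the replicate number as a block, and adjusted p = 0.301 with an estimated correlation. Dlk1-Dio3 miRNAs were lower for 12 of 14 and higher for 0 (12 adjusted over the list alone), with a median of −4.43, or −2.85 at bounds. Their camera adjusted p was 0.201, 0.0466 and 0.0453 without MM3MG-Her2 replicate 2 and TUBO cells replicate 2, and 0.0103 with the replicate number as a block. The remaining lists had camera adjusted p values of 0.760 (let-7, 4 of 9 higher, 0 lower, 4 adjusted over the list alone), 0.822 (miR-17-92, 3 higher and 4 lower, 7 adjusted over the list alone), 0.822 (oncomiRs, 7 higher and 6 lower, 13 adjusted over the list alone), 0.760 (tumour suppressors, 2 higher and 5 lower, 7 adjusted over the list alone), 0.822 (neuronal, 3 higher and 1 lower, 4 adjusted over the list alone) and 0.822 (star strands, 3 higher and 6 lower, 7 adjusted over the list alone). Tumour suppressors and star strands had medians of 0.12 and 0.03 while camera placed them lower. miR-3107-5p/miR-486-5p was lower by −2.07 (−2.68 without MM3MG-Her2 replicate 3), and both Sfmbt2 members were lower.

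Exosomes were compared with TUBO cells to ask what the particles hold relative to the cells that secrete them. Neither miR-9-5p nor miR-30a-5p passed the threshold: miR-9-5p was 55501 ± 7953 CPM in exosomes (SD, n = 3; log2 change 0.27 ± 0.29, adjusted p = 0.488) and miR-30a-5p 98833 ± 24129 CPM (−0.27 ± 0.24, adjusted p = 0.386). Without TMM scaling, miR-30a-5p made up at most 11.4% of miRNA reads in an exosome library and at least 14.1% in a cell library. The sign of the miR-9-5p change turned with RLE (−0.01) and library-size scaling, and miR-30a-5p passed the threshold with all 15 libraries in one fit (−0.56) and with inserts of 20 to 24 bases (−0.62). Among the largest rises were miRNAs of blood cells. miR-451a-5p (chromosome 11, 78073170 to 78073241), the miRNA of red cells, had 0 reads in TUBO cells and 992 ± 144 CPM in exosomes, at least 469-fold higher. miR-144-5p from the same transcript was at least 192-fold higher, and miR-3107-5p/miR-486-5p rose by 6.92 ± 0.58 (adjusted p = 1.1e-05) to 14108 ± 8036 CPM. Whether these reads came from TUBO cells or from serum in the medium cannot be read from this comparison. miR-6539-5p, under 100 CPM in both groups, had 0 reads in exosomes and 120 in TUBO cells, at least 24.9-fold lower. Among miRNAs with at least 100 CPM in either group falls were smaller: miR-92-5p by 2.69 ± 0.40 (adjusted p = 1.9e-05), miR-222-3p by 1.71 ± 0.25 (adjusted p = 1.5e-05), miR-29b-3p by 1.70 ± 0.38 (adjusted p = 0.0014) and miR-7-5p by 1.18 ± 0.26 (adjusted p = 0.0014).

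Of 239 miRNAs, 93 passed between exosomes and TUBO cells, 59 higher and 34 lower, and 154 did not overlap (64.4%, against 10% by chance). miR-126a-5p of endothelial cells, miR-409-3p, miR-3470b-3p and miR-3470a-3p had 0 reads in TUBO cells and were at least 71.3-fold, 64.3-fold, 63.2-fold and 49.8-fold higher; miR-142-5p had 1, a ratio of 405 (counting interval 72.1 to 16065). Its fitted log2 change of 8.19 was 9.16, 7.60 and 7.48 without TUBO cells replicate 1, 2 and 3. Whether reads assigned to miR-3470 are miRNAs or fragments of repeats was not tested. Further falls were miR-29c-3p (−1.48), miR-99a-3p (−1.31), miR-145a-5p (−1.31, not past the threshold with limma voom, at −1.49) and miR-27a-5p (−1.28). The share of rises was 63.4% under TMM with a median change of 0.09, and 41.8% and −0.20 with RLE, 43.1% and −0.19 with library-size scaling, so most small changes have no settled direction.

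All 5 tested blood cell and serum miRNAs were higher in exosomes than in cells (5 adjusted over the list alone), with a median of 7.48, or 6.92 at bounds (camera adjusted p = 1.05e-05, adjusted p = 0.0245 with an estimated correlation). All 6 tested Dlk1-Dio3 miRNAs, which TUBO cells nearly lacked, were higher too (6 adjusted over the list alone), with a median of 5.69, or 5 at bounds, including miR-379-5p (4.97 ± 0.52, adjusted p = 2.3e-07) and miR-127-3p (6.35 ± 0.61; 5.57 without exosome replicate 3 and 5.75 without TUBO cells replicate 3). Their camera adjusted p was 1.05e-05, and adjusted p = 0.286 with an estimated correlation. The low-count filter kept 6 of 31 Dlk1-Dio3 and 5 of 8 blood features with reads. Members scarce in cells pass it only through exosomes or supernatant, so it favours rises, and both camera p values share this limit. Over all its features the Dlk1-Dio3 list held 0.0851% ± 0.0395 of miRNA reads in exosomes and 0.00166% ± 0.00203 in cells (SD, n = 3). Progesterone receptor candidates had 3 of 12 higher and 0 lower (3 adjusted over the list alone): miR-126a-3p, with 0 reads in cells and at least 45.6-fold higher, and miR-26b-5p (0.70) and miR-181a-5p (0.62). With RLE these were 0.41 and 0.34 and did not pass, nor did they without exosome replicate 1 (0.40 and 0.25), exosome replicate 2 (0.62 and 0.48) or any 1 TUBO cell library (0.34 to 0.48 and 0.26 to 0.35). The summed share of these candidates was lower, at 26.8% ± 3.98 of miRNA reads in exosomes and 31.2% ± 0.625 in cells (SD, n = 3, exact permutation p = 0.1, the smallest possible). The let-7 list had 4 of 9 higher and 0 lower (7 adjusted over the list alone), led by let-7c-5p (1.13), and the miR-17-92 list 2 of 9 higher, miR-93-5p (1.49) and miR-25-3p (1.11), and 1 lower, miR-92-3p (−0.60), 3 of them adjusted over the list alone. miR-25-3p did not pass without any 1 TUBO cell library (0.79 to 0.87), nor miR-92-3p with upper-quartile scaling (−0.54).

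Of the other lists in exosomes against cells, epithelial miRNAs had 2 of 7 higher, miR-200c-3p (0.73) and miR-203-3p (0.67), and 1 lower, miR-141-3p (−0.92), 3 of them adjusted over the list alone. With RLE these rises were 0.45 and 0.39 and did not pass, nor did they without exosome replicate 1 (0.50 and 0.33) or any 1 TUBO cell library (0.35 to 0.51 and 0.30 to 0.42), nor miR-200c-3p without exosome replicate 3 (0.55) and miR-203-3p without exosome replicate 2 (0.42). Mesenchymal miRNAs had 2 of 4 higher, miR-10b-5p (5.92 ± 0.52) and miR-199a-3p/miR-199b-3p (2.14), and 1 lower, miR-145a-5p, 3 of them adjusted over the list alone. Without TUBO cells replicate 2 the 2 rises were 6.80 and 2.88, without replicate 1, 5.30 and 1.5, and miR-10b-5p was 5.28 without replicate 3. OncomiRs had 4 of 13 higher and 3 lower (7 adjusted over the list alone), with miR-24-3p at −1.01 and miR-31-5p at −0.98, and tumour suppressors 1 of 12 higher, miR-497-5p (3.89; 3.13 without TUBO cells replicate 3), and 4 lower (5 adjusted over the list alone). The neuronal list had 1 of 4 higher, miR-132-3p (1.18), and 0 lower (1 adjusted over the list alone), and star strands 4 of 17 higher and 6 lower (12 adjusted over the list alone), led by miR-30a-3p (1.43). Camera adjusted p was 0.849 for progesterone receptor candidates, epithelial, miR-17-92, oncomiR and neuronal lists, 0.730 for mesenchymal, 0.503 for let-7, 0.0822 for tumour suppressors and 0.0588 for star strands. The last was 0.0393, 0.0383 and 0.0365 without TUBO cells replicate 1, 2 and 3. For epithelial miRNAs and oncomiRs camera pointed down while the medians were 0.03 and 0.24. No muscle miRNA was tested, and the only Sfmbt2 feature tested, miR-466q-5p/miR-466i-5p/miR-466k-5p, was 1.56 with 19 reads against 12 (adjusted p = 0.039), and 0.79 without TUBO cells replicate 1.

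Exosomes were set against the supernatant left after their isolation to compare the particle with the particle-depleted fraction of one medium. let-7f-5p was 4.56 ± 0.23 higher in exosomes (SE, n = 3 per group, adjusted p = 6.9e-12), at 37946 CPM against 1566, and miR-9-5p was 3.55 ± 0.33 higher (adjusted p = 1.2e-07), at 55501 CPM against 4657 ± 2474. miR-21a-5p was 2.98 ± 0.26 higher and miR-30a-5p 1.36 ± 0.24 higher (adjusted p = 7.1e-05). On the supernatant side, miR-328-3p was −5.43 ± 0.30 (adjusted p = 1.4e-11; 147 against 6129 CPM), let-7d-3p −5.18 ± 0.29, and miR-423-5p −4.51 ± 0.27. miR-92-3p, the leading miRNA of the supernatant, was −2.90 ± 0.20. The changes ran against base composition: over 239 miRNAs, which are not independent replicates, the Spearman correlation of log2 change with GC share was −0.566, and called miRNAs higher in supernatant had a median GC share of 54.5% against 40.9% for those higher in exosomes.

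Of 239 miRNAs, 156 passed between exosomes and supernatant, 89 higher in exosomes and 67 lower, and 158 did not overlap (66.1%, against 10% by chance). After the linear GC trend of each library was removed 141 passed, 117 of them among these 156 and 113 in the same direction. The median change was 0.45, and rises made up between 55.5% and 58.6% of calls under all scalings tried. miR-144-5p, miR-142-5p and miR-126a-5p had 0 reads in supernatant and were at least 28.2-fold, 19.8-fold and 10.5-fold higher in exosomes, miR-451a-5p had 2 reads, a ratio of 103 (counting interval 28.5 to 855), and miR-190a-5p had 1, a ratio of 42.7 (7.58 to 1697). Supernatant replicate 1 decided both values: without it the fitted changes of miR-451a-5p and miR-190a-5p went from 6.59 to 11.36 and from 5.23 to 9.06, and without replicate 2 they were 5.91 and 4.58. miR-7-5p was 3.99 ± 0.48 higher (4.86 without supernatant replicate 2) and miR-542-3p 3.72 ± 0.49. Further miRNAs higher in supernatant were miR-3473b-3p/miR-3473e-5p (−5.62), miR-1934-3p (−4.97; −6.03 without exosome replicate 2), miR-204-3p (−4.91), miR-92b-3p (−3.96) and miR-8103-3p (−3.95). Whether reads assigned to miR-8103 are miRNAs or fragments of other RNAs was not tested.

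Progesterone receptor candidates had 10 of 12 higher in exosomes than in supernatant and 1 lower, miR-30d-5p (11 adjusted over the list alone), with a median of 2.27, led by miR-26b-5p (3.40) and miR-30c-5p (2.40) (camera adjusted p = 0.00350, adjusted p = 0.554 with an estimated correlation). let-7 members had 7 of 9 higher, such as let-7a-5p (3.39), and 2 lower, let-7b-5p (−1.19) and let-7c-5p (−0.85), 9 of them adjusted over the list alone, with a median of 2.60 (camera adjusted p = 0.0314, adjusted p = 0.0785 with the replicate number as a block, adjusted p = 0.576 with an estimated correlation). The miR-17-92 list had 7 of 9 higher and 2 lower, miR-92-3p and miR-25-3p (9 adjusted over the list alone). Its summed share was lower, at 10.4% of miRNA reads in exosomes and 34.7% in supernatant. Blood cell and serum miRNAs had 4 of 5 higher and 0 lower (5 adjusted over the list alone), with a median of 6.59, or 2.31 at bounds, and Dlk1-Dio3 miRNAs 5 of 6 higher and 0 lower (5 adjusted over the list alone), with a median of 3.15, or 2.47 at bounds. Epithelial miRNAs had 4 of 7 higher and 1 lower (5 adjusted over the list alone), mesenchymal 2 of 4 higher and 0 lower (2 adjusted over the list alone), oncomiRs 6 of 13 higher and 2 lower (8 adjusted over the list alone), tumour suppressors 3 of 12 higher and 2 lower (4 adjusted over the list alone), neuronal 0 of 4 higher and 2 lower (2 adjusted over the list alone), and star strands 4 of 17 higher and 4 lower (8 adjusted over the list alone). Camera adjusted p was 0.248 for miR-17-92, blood and Dlk1-Dio3, 0.478 for epithelial, mesenchymal, oncomiR and neuronal lists, 0.980 for tumour suppressors and 0.883 for star strands. For the last pair camera pointed down while the medians were 0.69 and 0.45. miR-466q-5p/miR-466i-5p/miR-466k-5p of the Sfmbt2 cluster was −1.97, with 19 and 17 reads.

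Supernatant was compared with TUBO cells to ask how far the particle-depleted medium differs from the cells. miR-92-3p and miR-25-3p rose by 2.30 ± 0.20 and 2.39 ± 0.24 (SE, n = 3 per group, adjusted p = 6.4e-09 and 4.6e-08), and let-7d-3p by 5.89 ± 0.30 (adjusted p = 6.4e-12), from 173 to 8208 CPM. miR-9-5p fell by 3.28 ± 0.32 (adjusted p = 2.5e-07), miR-30a-5p by 1.64 ± 0.25 (adjusted p = 8.3e-06) and miR-21a-5p by 2.73 ± 0.26. let-7 miRNAs separated: let-7f-5p fell by 4 ± 0.23, while let-7b-5p and let-7c-5p rose by 2.23 and 1.98. Of 239 miRNAs, 177 passed, 86 higher and 91 lower, and 177 did not overlap (74.1%, against 10% by chance). After the linear GC trend of each library was removed 143 passed, 124 of them among these 177 and 121 in the same direction. With at least 100 CPM in either group, miR-3473b-3p/miR-3473e-5p (7.22) and miR-3470b-5p (6.33) rose most besides let-7d-3p, and miR-27b-5p, miR-18-5p and miR-27a-5p had 0 reads in supernatant, at least 11.8-fold, 10.3-fold and 7.93-fold lower. The Spearman correlation of change with GC share was 0.536 over miRNAs, against −0.000564 for exosomes against cells. The median change was −0.12, and −0.40 with RLE and −0.44 with library-size scaling.

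**Figure D4:**
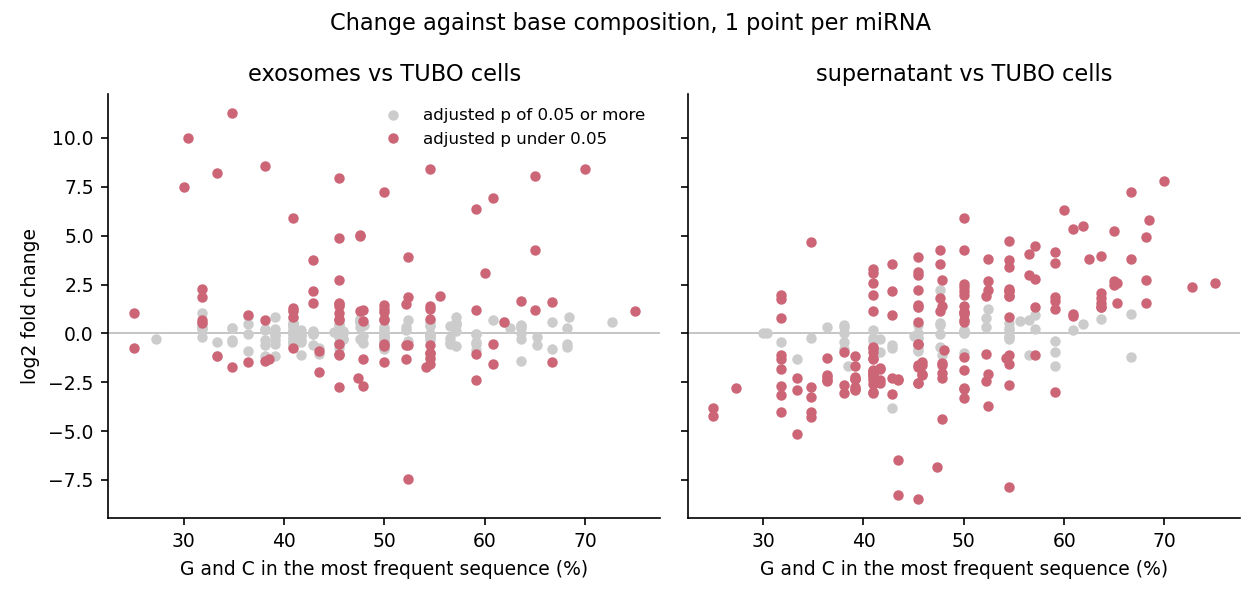
log2 fold change against TUBO cells of each of 239 miRNAs plotted over the share of G and C in its most frequent sequence (%), for exosomes on the left and supernatant on the right; coloured points have an adjusted p under 0.05. The correlation over miRNAs was −0.000564 for exosomes and 0.536 for supernatant.

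Progesterone receptor candidates had 9 of 12 lower in supernatant than in cells and 1 higher, miR-30d-5p (0.57), 10 of them adjusted over the list alone, with a median of −1.75 (camera adjusted p = 0.00601, adjusted p = 0.664 with an estimated correlation). let-7 had 7 of 9 lower and 2 higher (9 adjusted over the list alone), with a median of −2.22 and camera adjusted p = 0.0572, which lay between 0.0121 and 0.0385 when any 1 library of either group was left out. miR-17-92 had 7 of 9 lower and 2 higher (9 adjusted over the list alone), star strands 10 of 17 lower and 4 higher (14 adjusted over the list alone), tumour suppressors 7 of 12 lower and 3 higher (10 adjusted over the list alone), oncomiRs 6 of 13 lower and 3 higher (9 adjusted over the list alone), such as miR-31-5p (−2.62), and epithelial miRNAs 3 of 7 lower and 1 higher (4 adjusted over the list alone). Mesenchymal miRNAs had 2 of 4 higher and 2 lower (4 adjusted over the list alone), neuronal 2 of 4 higher and 0 lower (2 adjusted over the list alone), blood cell and serum 3 of 5 higher and 0 lower (3 adjusted over the list alone), with miR-3107-5p/miR-486-5p at 5.34 (4.53 without supernatant replicate 3), and Dlk1-Dio3 3 of 6 higher and 0 lower (3 adjusted over the list alone). These counts rest on few reads: miR-451a-5p had 2 against 0 and did not pass without supernatant replicate 1, and without supernatant replicate 2 neither miR-409-3p, with 2 against 0, nor miR-411-5p, with 6 against 2 (4.28, and 3.78 without it; 3.60, 6.09 and 3.60 without TUBO cells replicate 1, 2 and 3), passed. Without any 1 TUBO cell library miR-409-3p did not pass either. Blood medians were 3.91, or 0 at bounds, and Dlk1-Dio3 medians 3.19, or 1.11 at bounds. Camera adjusted p was 0.339 for miR-17-92, 0.517 for star strands, 0.501 for epithelial, oncomiR, tumour suppressor and neuronal lists, 0.870 for mesenchymal and 0.478 for blood and Dlk1-Dio3. Summed shares of miRNA reads went against the member counts for let-7 (17.0% in supernatant, 13.3% in cells), miR-17-92 (34.7% and 10.3%) and star strands (1.58% and 0.781%). Those of the progesterone receptor, tumour suppressor, oncomiR and epithelial lists were lower in supernatant, as their member counts were. miR-466q-5p/miR-466i-5p/miR-466k-5p was 3.53 (adjusted p = 5.2e-05; 2.87 without TUBO cells replicate 1).

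Exosomes and supernatant shared 56 changes from TUBO cells in the same direction, 32 higher and 24 lower, against 34.2 if calls were independent. Opposite changes numbered 14. The correlation of the changes was 0.414, against 0.349 in simulated data with the shared control and no true effect. As for the cell lines, that simulated correlation is high by design and cannot judge the real one. The covariance of the changes was 2.44, against 0.0483 simulated and 0.0742 at most. The simulation held only the spread between libraries, so a trait of the TUBO cell libraries as a group stays in both changes. Part of the excess of shared calls may come from the shared control. miR-10b-5p and miR-3107-5p/miR-486-5p rose and miR-31-5p and miR-222-3p fell in both.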

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

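The tests of the size of changes, read spill, cell-library depth, mesenchymal loss and scaling were chosen only after the result was seen, and the read minimums and exclusions of the substitution search were changed after a first look; the other tests here were set earlier.

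miRNAs that differ between both Her2 lines came first. Of the miRNAs past the threshold in MM3MG-Her2 and in TUBO cells, each against MM3MG, 40 changed in opposite directions with the direct difference also past the threshold, among them miR-9-5p (−1.60 and 7.79), miR-146b-5p (−2.16 and 3.02) and miR-196a-5p (0.70 and −7.80). The direct comparison called 207 miRNAs. The lines differ in origin as well as in how Neu was introduced, so neither can be named as the reason.

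Outside the miRNAs, snRNA fragments had 2.07 times the share in MM3MG-Her2 that they had in MM3MG, transcripts outside the named classes 3.84 times, and reads matching no annotated RNA 2.36 times. In exosomes against TUBO cells, snRNA fragments had 11.2 times the share, Y, 7SL, 7SK and vault RNAs 7.12 times and mRNA fragments 2.32 times. In supernatant the ratios were 16.5 for snRNAs, 2.50 for Y, 7SL, 7SK and vault RNAs and 3.41 for unmatched reads. In each of these no library of one group overlapped the other (exact two-sided permutation p = 0.1, n = 3 per group, the smallest possible). These classes stood out because they lie outside the comparisons of the report and exceeded the level in the reference cells. Shares of reads are relative, and a gel band of miRNA size takes only short fragments of these RNAs. A source of the exosome and supernatant fragments in the serum of the medium was not tested.

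Supernatant lay further from TUBO cells than exosomes did, with 177 miRNAs past the threshold against 93, a ratio of 1.90 (1.44 to 2.39 when 1 library was left out). The median absolute log2 change was 1.89 against 0.593, a ratio of 3.18 (2.49 to 3.13). For this size of the changes 3 explanations are argued against as the whole cause. After the linear GC trend of each library was removed the medians were 1.39 and 0.608, a ratio of 2.28 (1.81 to 2.39), with every library thinned to the smallest total the ratio was 2.74 (2.46 to 3.02), and with the 5 most abundant miRNAs left out 3.05 (2.51 to 3.22), where 1.5 was required. For the number of calls, thinning cannot judge depth. Fewer reads cost calls, so the lower depth of supernatant would lower its count rather than raise it. At equal depth 110 and 35 passed, a ratio of 3.14 (2.03 to 5.48). Thinning cost exosomes a larger part of their calls, so a rise of this ratio from 1.90 was built in. GC bias and a few miRNAs taking most of the counts stay open for the number of calls. After the GC trend was removed the ratio of calls was 1.54, past the bound of 1.5 set against it, yet it ranged from 1.18 without supernatant replicate 3 to 1.86, so it did not clear that bound by more than its spread. With the 5 most abundant miRNAs left out it was 1.85 (1.38 without supernatant replicate 2, up to 2.42). Supernatant also had more short inserts, with 28.9% of reads at 20 bases or fewer against 15.9% in exosomes and 10.1% in TUBO cells. With inserts of 20 to 24 bases alone 164 and 99 miRNAs passed, 160 and 73 of them shared with the full data. Neither loss of whole miRNAs through breakdown nor RNA selection in the medium was tested, and a difference in how that fraction was prepared is confounded with it.

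Blood cell and serum miRNAs, such as miR-451a-5p and miR-3107-5p/miR-486-5p, held 1.56% of miRNA reads in exosomes and 0.0144% in TUBO cells, with 2.48% in exosome replicate 3 and 1.04% in replicate 1. The floor of 3 reads in TUBO cells was at most 0.0637 of the mean CPM in exosomes for every tested member. The low-count filter largely fixed this, since it keeps members scarce in cells only through exosomes or supernatant. That floor thus says little about low depth of the cell libraries. Low depth is argued against by the read totals, as cell libraries averaged 478794 miRNA reads and exosome libraries 297812. Spill from another library of this series is argued against, since the lowest exosome library held 1.47 times the highest share of any other library. RNA of another organism from the FCS stays open. Reads with 1 fixed substitution were at least 10 times as frequent in exosomes as in cell libraries for 2 of 211 miRNAs searched. The test required 3, and neither of these 2 is on the blood list. Supernatant had no such excess, with 6 reads of miR-155-5p at the site. miR-151-3p had a substitution at position 10, counted from 1 at the 5' end of its main sequence, in 159 of 3239 exosome reads (4.09%, 5.61% and 5.21% in replicates 1 to 3), 0.0351% of cell reads and 1 of 3532 supernatant reads, and miR-155-5p one at position 12 in 26 of 63 exosome reads and 0 reads of the other groups. Serum of another species may be a source of part of the exosome reads, but no bovine reference was used here, and miRNAs with the same sequence in both species give no such reads; uptake or expression by TUBO cells was not tested.

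Dlk1-Dio3 miRNAs were lower in MM3MG-Her2 than in MM3MG, with a median of −4.47 and a range from −6.29 to −3.58. Loss of cells that express stromal miRNAs in general is argued against: the median fall of the mesenchymal list was 0.191 of that of the cluster, and of its members miR-10b-5p alone fell as far (−6.09). Scaling is argued against too, since the highest median under RLE, library-size and upper-quartile scaling was −4.52 and 14 of 14 members stayed past the threshold in each. What lowered the cluster was not tested, and with 1 transduced line an effect of Neu cannot be separated from other changes in that line.

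Splits of the 6 libraries of each comparison into other groups of 3 number 10 with the real one, too few for a share under 0.05. In each of the 6 comparisons 1 split, the real one, gave as many calls (175, 231, 207, 93, 156 and 177 in the order of the report), and the highest of the others gave 0. Every other split mixes both groups, so their difference enters the spread within groups. The 0 therefore says little about how many real calls are right.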

How the results depend on the processing

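Exact matches alone, inserts of 20 to 24 bases, unnamed hairpins added, the blood list left out and lists without the libraries farthest from their group were alternatives chosen after the data were seen.

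Counts of changed miRNAs stayed within 1.5 times in 132 of 135 recalculations, overlaps in 50 of 51. Ranges were 116 to 203 for MM3MG-Her2 against MM3MG, 187 to 324 for TUBO cells against MM3MG, 165 to 252 for TUBO cells against MM3MG-Her2, 35 to 126 for exosomes against cells, 107 to 178 for exosomes against supernatant and 110 to 209 for supernatant against cells. With a 2-fold minimum MM3MG-Her2 against MM3MG had 116, since fewer miRNAs qualify. Thinned to the smallest library, exosomes against cells had 35 (33 shared with the full data), supernatant against cells 110 (108 shared) and their overlap 18, so depth limits these counts. With the replicate number as a block, counts were 175, 229, 207, 86, 151 and 170 in the order of the report. Of the single miRNAs, 4837 of 5031 recalculations kept direction and side of the threshold, 178 lost the threshold, 2 gained it and 14 reversed.

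Reversals, whose cause was not tested: in TUBO cells against MM3MG with all 15 libraries, let-7b-5p was −0.27 and let-7c-5p −0.34. In TUBO cells against MM3MG-Her2, miR-25-3p (0.31) was −0.18 with upper-quartile scaling, −0.24 with all 15 libraries and −0.26 to 0.40 with 1 library left out. In exosomes against cells, miR-9-5p (0.27, not past the threshold) was −0.011 with RLE, −0.0025 with library size, −0.020 with DESeq2, −0.0073 with all 15 libraries, −0.051 with inserts of 20 to 24 bases, and −0.060 to 0.36 with 1 library left out.

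Lists kept their call in 594 of 630 recalculations, 17 gained one and 19 lost it. Lists past the threshold numbered 4, 3, 3, 2, 2 and 1, and 0, 0, 0, 1, 0 and 0 with an estimated correlation. With the replicate block exosomes against supernatant had 1, as let-7 had an adjusted p of 0.0785, and in TUBO cells against MM3MG-Her2 Dlk1-Dio3 gained the call (0.0103) and progesterone receptor candidates lost it (0.0940). Supernatant against cells had 2 whichever library was left out. Summing values listed under several precursors was not run, as the deposited files name no precursor.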

Other observations

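All tests in this part were set earlier; the single genes named were chosen after their values were seen.

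Small nucleolar RNAs, which guide rRNA modification in the nucleolus, had lower shares of all reads outside the cells. Only small RNA genes with the most reads summed over all libraries were counted singly, which favours genes abundant in cells. Of 38 such snoRNA genes, 34 had a lower share in all exosome libraries than in any TUBO cell library and 2 a higher one. Their median ratio was 0.0976. In supernatant 32 were lower and 2 higher, with a median ratio of 0.0215. For the whole class of snoRNAs and scaRNAs the ratios were 0.163 in exosomes and 0.317 in supernatant. Those of miRNA hairpins were 0.779 and 0.407, so in supernatant the class as a whole fell little further than miRNAs did. Exceptions included Snord14c/Snord14d, at 1.92 times the cell share in exosomes and 2.43 in supernatant, and U3 (Rnu3b1/Rnu3b2/Rnu3b3), at 10.1 times in supernatant and 0.320 in exosomes. Y RNA fragments differed by gene: Rny1, which binds Ro60, held 0.405% of exosome reads against 0.0327% in cells, a ratio of 12.4 (2.90 in supernatant), whereas Rny3 had ratios of 5.35 in exosomes and 0.157 in supernatant. Vaultrc5 had ratios of 8.64 and 5.76. Of the spliceosomal RNAs, Rnu2 had 23.8 in exosomes and 19.0 in supernatant, and Rnu1 6.11 and 23.6, but Rnu5g was lower in both, at 0.308 and 0.103 (with supernatant reads in replicate 2 alone), and Rnu11 was lower in exosomes (0.363) and higher in supernatant (2.60). Mitochondrial fragments were scarce in supernatant, at 0.0108 times the cell share for mt-Ts2 and 0.0165 for mt-Rnr2. Whether the fragments in exosomes and supernatant came from TUBO cells or from serum in the medium was not tested. MM3MG-Her2 and TUBO cells both had lower snoRNA shares than MM3MG, with 24 and 26 of 38 lower in all libraries, 2 and 3 higher, and median ratios of 0.535 and 0.514. These are shares of all reads, and unmatched reads made up 39.9% in MM3MG-Her2 against 16.9% in MM3MG. There miRNA hairpins had a ratio of 0.682, beside 0.556 for snoRNAs and scaRNAs, so the fall in MM3MG-Her2 was not separated from that excess. In TUBO cells these ratios were 0.996 and 0.541.

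A hypothesis was that miRNAs from one primary transcript change together in cells and are sorted together into particles. For miRNAs whose hairpins lie within 10 kb on 1 strand, the share of variance of log2 changes between clusters was 0.929 for MM3MG-Her2 against MM3MG and 0.964 for TUBO cells against MM3MG (71 miRNAs in 24 clusters; permutation p = 1e-04 each, the smallest that 10000 shuffles can give). Without chromosome 12, which holds the Dlk1-Dio3 cluster, it was 0.708 and 0.937. For exosomes against cells it was 0.893 (60 miRNAs in 24 clusters), and 0.867 without chromosome 12 (permutation p = 0.0022). For supernatant against cells it was 0.0974, within the range of shuffled clusters, whose 95th percentile was 0.252 (permutation p = 0.270). Shared transcripts are thus a candidate explanation for the changes between cell lines and for those of exosomes, whose risen clusters include miRNAs hardly found in TUBO cells, so a source outside these cells was not separated from sorting. In supernatant miRNAs of one cluster went apart, as miR-92-3p (2.30) and miR-20a-5p (−2.88; −3.61 without supernatant replicate 1) did, and the GC trend given for that comparison is one difference between such neighbours that stays open.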
